A study of Mus musculus with 8 samples.

How the data were processed

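The series holds tomo-seq data of mouse oral mucosa. In tomo-seq a frozen tissue block is cut into serial sections, and the RNA of each section gets its own barcode before sequencing, so that expression can be followed through the depth of the tissue. Wild-type C57BL/6J mice gave 8 samples, 2 replicates of each of 4 sites: buccal mucosa (the inner cheek), dorsal tongue (the upper surface), hard palate and ventral tongue (the underside). Each sample had 20 sections of 14 µm, 280 µm of tissue in all. The labels number the replicates and do not say whether they came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

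Per the labels' protocols, RNA was extracted from single sections, made into CEL-seq2 libraries (3' end counting with unique molecular identifiers, UMIs) and sequenced on a NextSeq500. Trim Galore 0.6.10, STAR 2.7.9a and the build GRCm38 are named in the submitters' processing notes. The counting program and its settings are not given in the sources used here. The deposited files hold 3 tables of counts per sample, per gene and section: counts of distinct UMIs, counts of reads, and estimated counts of transcripts corrected for UMI collisions, as the values show. The UMI counts were used here unless stated otherwise. They stop near 4096 per gene and section, the number of possible UMIs, so differences of the most abundant genes are compressed. Reads and estimated transcripts are quoted for named genes near that limit.

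Totals ran from 7830471 UMIs (buccal mucosa replicate 2) to 26376536 (hard palate replicate 2), with 1.91 to 2.74 reads per UMI. Over all samples 33549 entries had a count. Of these 413 named several genes at once and held 0.185% to 0.251% of a sample's UMIs. These stayed in the library sizes and tests and were never named. A symbol was found for 33023 of the 33136 entries that named 1 gene, and gene positions were taken from the GENCODE annotation of GRCm38. Whether reads shared by near-identical genes were split or dropped is not given in the sources used here, so values of the keratin-associated protein, hair keratin and Sprr2 families are uncertain between members. A count of 0 allows up to 3 UMIs of the total, for counting error only.

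Sections with at least 1000 UMIs were kept, which was every section. The order of the sections was checked by the mean Spearman correlation of adjacent section numbers over 2000 genes against 100000 random orders of the same sections. Each section was scored by the mean log2 CPM of 20 genes shared by stratified squamous epithelia, smoothed by a running median over 3 sections, and Otsu's threshold split the sections of each sample into epithelium-rich and epithelium-poor. These names say how that list is distributed and nothing of which cells a section held; the genes of the list were left out of counts and names in comparisons of the regions.

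UMI counts were summed over the sections of a sample or of its regions. Genes were kept by edgeR's filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F-test, R 4.3.3), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Each site was compared with the mean of the other 3, dorsal with ventral tongue, and the 4 sites with each other by 1 test of any difference. The mean of the other 3 sites was taken on the log scale, while the CPMs quoted beside it are arithmetic means over samples. A site near 0 CPM can thus make a fold change much larger than the ratio of the CPM means. All 8 samples shared 1 estimate of the spread. The regions were compared with the sample as a block, and the dependence of the region difference on the site by an interaction test. Epithelium-poor sections near an epithelium-rich section were compared with those farther away; at the planned distance of 10 section numbers only 1 sample had at least 5 sections of each kind, so a distance of 5 numbers, also fixed in advance, was used. Gene lists of cell type markers, epithelial differentiation, signalling pathways and transcription factors were tested with fry (limma 3.58.1), which asks whether a list's genes move on balance one way; its mixed test asks whether they change in either direction. Camera with an estimated correlation was the alternative. In the text, a list member rose or fell where its own adjusted p passed over all genes tested. CPM values are means ± SD over samples. The SE of a fold change was derived from the test, as its size divided by the square root of the F statistic. It is no separate estimate, and it is uncertain where a fold depends on the prior count.

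The samples, designs, lists, alternatives and the rule for named genes were fixed before the data were examined. For a site the rule takes the 5 largest rises and the 3 largest falls among genes that passed, had a mean of at least 50 CPM in the higher group and did not overlap between the sides. Between the regions it takes the 10 largest rises and 6 largest falls of the same sign in every sample, and for a described list up to 4 members with the smallest adjusted p, whether or not they passed. The lists described here were picked from all those tested after their results were seen. A fold against samples with 0 UMIs depends on the prior count, so CPMs are given with it.

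On simulated counts with the real means and library sizes, the comparison of 1 site with the others recovered 3% of 2-fold and 64% of 4-fold changes (16603 genes, biological coefficient of variation 0.4). The region comparison recovered 100% of both (15776 genes, coefficient 0.15) and the interaction 29% and 100% (15742 genes, coefficient 0.15). These coefficients were assumed and the same for every gene, and the changed genes were drawn only from those above a minimum count. Recovery in the real data, where the spread varied between genes, may be lower. The alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, read counts, estimated transcripts, 4 other rules for the regions, section minima of 300 and 3000 UMIs, the replicate number as a block, and each sample left out in turn. After the data were seen, 3 more were added: the first against the last 5 sections, the other sites without hard palate, and the counts without buccal mucosa replicate 2 beside the main ones. The list of barcode sequences of the series was not used. Results of some genes are not reported here.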

Results

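Oral mucosa from 4 sites of the mouse was profiled section by section to compare gene expression between the sites and through the depth of the tissue. Buccal mucosa, dorsal tongue, hard palate and ventral tongue each had 2 replicates, and each of the 8 samples had 20 sections. Total UMI counts were 16878956 and 7830471 in buccal mucosa replicates 1 and 2 and 21230278 and 20325813 in dorsal tongue. They were 17743983 and 26376536 in hard palate, and 16182531 and 20526538 in ventral tongue. Transcripts of the mitochondrial genome took 2.11% to 7.20% of a sample's UMIs, with the highest share in buccal mucosa replicate 2.

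Neighbouring sections resembled each other in every sample. The mean Spearman correlation across genes of adjacent sections was 0.895 to 0.962, against 0.746 to 0.913 over all pairs of sections of the same sample. Random orders of the sections gave a mean as high with p = 2e-05 in hard palate replicate 1 and p = 1e-05 in the other 7 samples (one-sided permutation test, 100000 resamples), the latter being the smallest p these resamples can give. The keratinocyte score was highest within the first 4 sections in the buccal mucosa and tongue samples, and at sections 12 and 10 in hard palate replicates 1 and 2. Sections 1 to 5 were epithelium-rich in 7 samples, and in hard palate replicate 1 epithelium-poor sections began at number 3. The numbers of epithelium-rich and epithelium-poor sections were 9 and 11 and 5 and 15 in buccal mucosa and 17 and 3 and 10 and 10 in dorsal tongue. They were 14 and 6 and 13 and 7 in hard palate and 9 and 11 and 7 and 13 in ventral tongue, for replicates 1 and 2 in turn. The score differed between the regions by 0.153 log2 units in hard palate replicate 1 and by up to 1.59 in buccal mucosa replicate 2. Epithelium-poor sections thus still held abundant keratinocyte transcripts, with mean scores of 7.39 to 8.94 outside buccal mucosa replicate 2, where it was 4.14. The split was made within each sample, so a region name does not mark the same score at each site. Epithelium-poor hard palate averaged 8.94 and 8.63 in replicates 1 and 2. Epithelium-rich sections of the other sites averaged 8.32 to 8.75 outside buccal mucosa replicate 2.

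**Figure D1:**
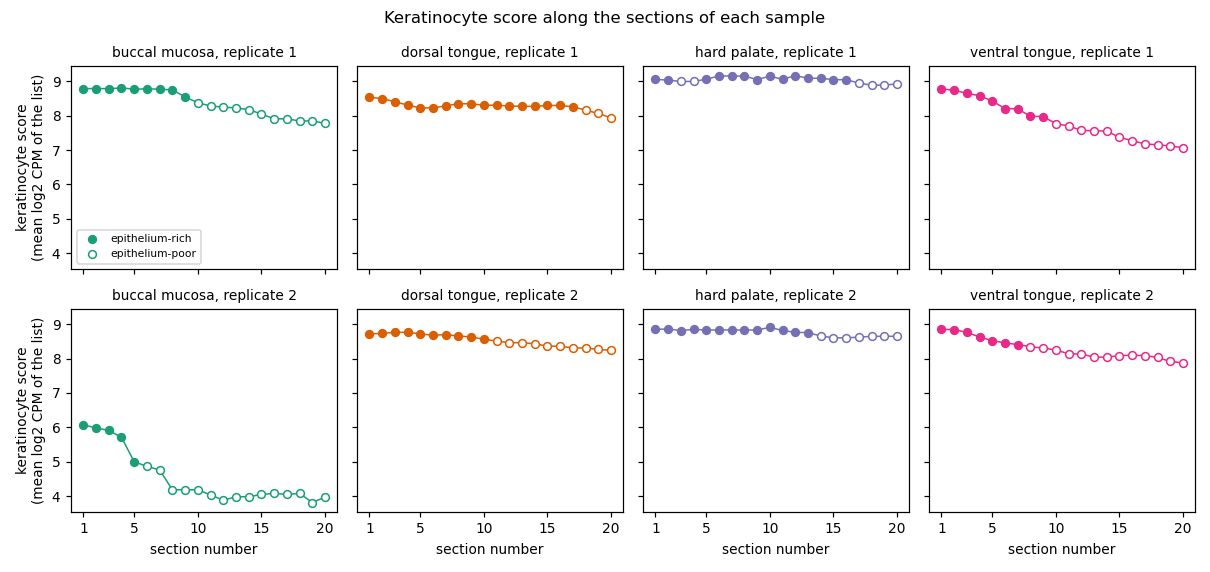
Keratinocyte score (mean log2 CPM of the region-defining genes, vertical axis) of each section against its number (horizontal axis) in the 8 samples, with the sections of both regions marked. The score of buccal mucosa replicate 2 averaged 5.74 and 4.14 in its regions, below every other sample.

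The samples differed in the cell types their transcripts came from. Keratinocyte and cornified envelope genes were low in buccal mucosa replicate 2. The cornified envelope list averaged 2.44 log2 units in its epithelium-rich and 1.81 in its epithelium-poor sections, against 7.07 to 8.31 in the other 7 samples. In the same sample salivary gland genes averaged 6.16 and 5.87, against 1.20 to 3.02 elsewhere, and adipocyte genes 7.34 and 7.18, against 2.35 to 4.02. Skeletal muscle genes were low in hard palate, at 3.22 and 1.87 in the epithelium-rich and 4.03 and 2.88 in the epithelium-poor sections of replicates 1 and 2, against 7.20 to 9.81 in all other samples. The Spearman correlation across genes between replicates, with genes not being independent replicates, was 0.782 in epithelium-rich buccal mucosa and 0.969, 0.956 and 0.965 in dorsal tongue, hard palate and ventral tongue. In epithelium-poor sections it was 0.834, 0.970, 0.940 and 0.963.

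**Figure D2:**
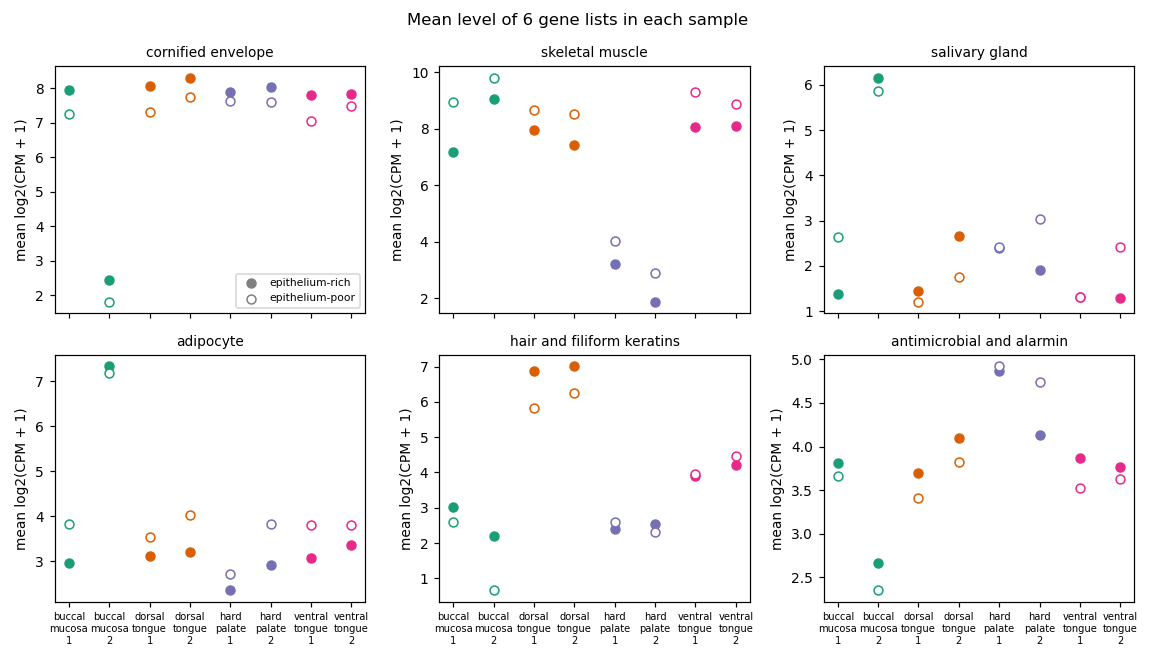
Mean log2(CPM + 1) of 6 gene lists (vertical axes) in each sample (horizontal axes), shown separately for epithelium-rich and epithelium-poor sections. Buccal mucosa replicate 2 had the lowest cornified envelope level (2.44 and 1.81) and the highest salivary gland level (6.16 and 5.87), and both hard palate samples had the lowest skeletal muscle levels.

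Between the regions, genes of late keratinocyte differentiation were higher in epithelium-rich sections and muscle, vessel and connective tissue genes were higher in epithelium-poor sections. Spink5, a protease inhibitor of the upper epidermis, had the largest rise that met the rule, with a log2 fold change of 1.05 ± 0.21 (SE; 858 ± 418 CPM against 483 ± 285, SD, n = 8; adjusted p = 0.00327). Krt17 rose by 0.90, the fatty acid elongase Elovl4 by 0.90, Ly6g6c by 0.84, the transcription factor Klf4 by 0.78 and Trim29 by 0.78. The arginase Arg1 rose by 0.78, the ribosomal RNA CT010467.1 by 0.78, the defensin Defb6 by 0.77 and the sphingomyelinase Smpd3 by 0.77. The largest falls were muscle genes and an enzyme of glycerol metabolism. The fast-fibre actinin Actn3 fell by 2.02, Ampd1 by 1.73, Mylk4 by 1.71, Gpd1 by 1.70, Asb11 by 1.67 and the myosin heavy chain Myh2 by 1.64. Each gene named by the rule had the same sign in 8 of 8 samples, which the rule required. Krt17 reached 4099 UMIs in 1 section, near the limit, and its rise was 0.82 in reads and 0.74 in estimated transcripts. Of 15174 genes tested 2246 were higher and 3149 lower in epithelium-rich sections. The split depended on scaling. With RLE 2887 were higher and 2692 lower, 51.7% against 41.6% higher, and the median of all genes moved by 0.0439 log2 units. Regions drawn by Krt5 and Krt14 gave 3399 genes.

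**Figure D3:**
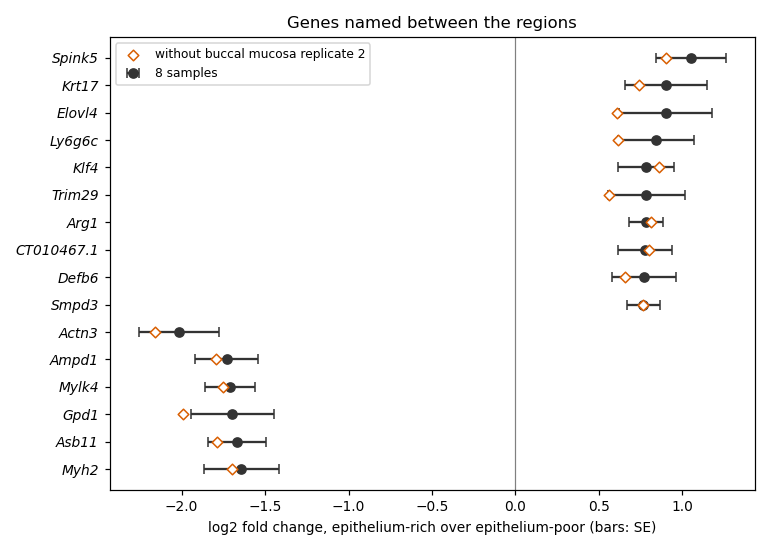
Log2 fold change between epithelium-rich and epithelium-poor sections (horizontal axis; bars, SE; n = 8 samples) of the genes named between the regions (vertical axis). Spink5 rose by 1.05 and Actn3 fell by 2.02.

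In the gene lists, 34 of 41 cornified envelope genes rose (36 adjusted over the list alone), led by Sbsn (0.69 ± 0.09 SE), the cornified envelope scaffold Ppl (0.66), Cdsn (0.67; 0.74 in reads and 0.72 in estimated transcripts) and Lce3a (0.53). Of 19 oral and stress-type keratins 10 rose (10 adjusted over the list alone), among them Krt78 (0.64), Krt80 (0.88), Krt6b (0.45; 0.53 in reads, 0.80 in estimated transcripts) and Krt6a (0.44; 0.46 and 0.72). Of 29 antimicrobial genes 12 rose and 1 fell (12 and 2 adjusted over the list alone), with Wfdc12 at 0.55, Wfdc5 at 0.62, S100a7a at 0.61 and Il1rn at 0.49. Skeletal muscle genes fell in 34 of 36 cases (34 adjusted over the list alone, where 1 rose), including Mybpc1 (-1.31), Casq1 (-1.45), Pygm (-1.20) and Actn2 (-1.29). Of 23 endothelial genes 18 fell (18 adjusted over the list alone), such as Tie1 (-0.87), Cdh5 (-1.05), Pecam1 (-0.83) and Cd93 (-0.66). Of 17 smooth muscle and pericyte genes 13 fell and 2 rose (13 and 2 adjusted over the list alone), with Synpo2 at -1.26, Abcc9 at -1.19, Rgs5 at -0.81 and Myh11 at -1.27. Of 16 adipocyte genes 10 fell and 1 rose (11 and 1 adjusted over the list alone), with Fabp4 at -1.54 and Lpl at -1.38.

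Of 38 genes of fibroblasts and fibrillar matrix 17 fell (20 fell and 2 rose adjusted over the list alone), with Fbn1 at -0.61, Mgp at -0.70, Pdgfrb at -0.57 and Mfap5 at -0.77. Of 21 Schwann cell and nerve genes 13 fell and 1 rose (14 and 1 adjusted over the list alone). The myelin genes Cnp and Prx fell by 0.66 and 1.00, and Erbb3 rose by 0.40. Of 8 red blood cell genes 6 fell (6 adjusted over the list alone), among them Hbb-bt (-0.86), Hbb-bs (-0.72), Hba-a2 (-0.68) and Hba-a1 (-0.63). By fry 10 lists moved on balance one way, 3 up and 7 down. Adjusted p was 0.000412 for cornified envelope, oral keratins and skeletal muscle, 0.00617 for endothelium and 0.00653 for smooth muscle. It was 0.00814 for adipocytes, 0.0124 for red blood cells, 0.0362 for nerve, 0.0426 for antimicrobial genes (0.051 without buccal mucosa replicate 2) and 0.0453 for matrix. With an estimated correlation none passed, the smallest being adjusted p = 0.0669. The regions were drawn from keratinocyte expression of the same sections. P-values between them, for genes and for lists, thus describe a contrast built from these data and are no independent test. Cell cycle genes missed the threshold as a list (13 of 30 rose, 14 adjusted over the list alone; adjusted p = 0.0606), with Tpx2, Birc5, Top2a and Mki67 at 0.46, 0.50, 0.48 and 0.45. Growth factor genes of the EGF and FGF families went both ways, 10 up and 9 down of 36 (10 and 11 adjusted over the list alone), with Fgf22 at 0.84 and Fgf1 at -0.93 (adjusted p of the mixed test 0.000642). Notch genes did too, 7 up and 5 down of 18 (7 and 5 adjusted over the list alone), with Notch1 at 0.45 and Dll4 at -0.73 (0.000803).

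Dorsal tongue stood out in the epithelium-rich sections by hard keratins and keratin-associated proteins, the building blocks of hair and of the filiform papillae. Krt31 was at 422 ± 2.73 CPM against 4.25 ± 4.08 in the other sites (SD, n = 2 and 6; log2 fold change 7.80 ± 0.32 SE, adjusted p = 0.000164) and Krt83 at 313 ± 16.3 against 2.80 ± 3.77 (8.16). Krt33a was at 129 ± 15.6 against 0.520 ± 0.369 (8.53) and Krt86 at 484 ± 10.3 against 1.45 ± 1.64 (9.08). The largest rises that met the rule were keratin-associated genes. They were Gm11559 (443 ± 280 CPM against 0.365 ± 0.426), Gm11555 (64.2 ± 38.4 against 0.0237 ± 0.0579) and Gm11595 (686 ± 300 against 1.15 ± 1.66), followed by Krtap4-2 (970 ± 253 against 1.87 ± 2.16) and Gm11564 (80.2 ± 43.3 against 0.111 ± 0.174). Their log2 fold changes of 11.32, 11.29, 11.20, 11.02 and 10.99 depend on the prior count, since 3 to 5 of the 6 other samples had no UMI, and reads shared within the family leave single members uncertain. Of 24 Krtap genes tested 21 were higher, and so were 31 of the 32 genes tested on chromosome 11 between 99550130 and 99993234 (GRCm38). Lgi2 and the homeobox gene Meis2 fell by 3.87 and 3.06, with Meis2 at 9.11 ± 3.25 CPM against 87.2 ± 54.7.

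By list, 11 of 20 hard keratin and partner genes rose in epithelium-rich dorsal tongue (14 adjusted over the list alone). The list had adjusted p = 0.00076 by fry and adjusted p = 0.00995 with an estimated correlation. Of 59 transcription factors that pattern the face, palate and tongue 4 rose and 2 fell (7 and 13 adjusted over the list alone; adjusted p of the mixed test 1.2e-05). On balance the list did not pass (fry adjusted p = 0.408, adjusted p = 0.745 with an estimated correlation). Tbx3 rose by 2.67 (112 ± 10.2 CPM against 18.7 ± 7.39, SD), Hand2 by 2.67 and Nkx2-5 by 4.17. Of 36 Wnt genes 2 rose and 1 fell (8 and 4 adjusted over the list alone). Apcdd1 rose by 2.27, Wnt3 by 3.13 and the secreted antagonist Sfrp2 fell by 4.18, while Fzd1 was at 0.98 (adjusted p = 0.109). Of 34 BMP and TGF-beta genes Bambi rose by 2.91 and Grem1 fell by 5.24 (3 and 1 adjusted over the list alone), with Smad6 at 1.14 and Id4 at 1.13 (adjusted p = 0.107 and 0.177). In all 156 genes were higher and 16 lower of 16485. Without buccal mucosa replicate 2 there were 634 and 161, including all 156 and 16. The count was 1530 and 795 without buccal mucosa replicates 1 and 2. It was 61 and 54 without those of dorsal tongue, 63 and 62 without those of hard palate, and 46 and 50 without those of ventral tongue. Of the 22 named genes 7 passed in every one of these fits (Gm11559, Gm11564, Gm11595, Krt31, Krt33a, Krt83 and Krt86). Against buccal mucosa and ventral tongue alone 112 genes passed, and adjusted p was 0.0809 for Lgi2, 0.264 for Hand2, 0.396 for Nkx2-5, 0.0769 for Apcdd1, 0.0955 for Wnt3, 0.0563 for Sfrp2 and 0.0712 for Grem1. The folds of Apcdd1 (2.27), Wnt3 (3.16), Sfrp2 (-4.19) and Grem1 (-5.05) stayed about as large, while Hand2 was at 1.22, Nkx2-5 at 1.84 and Lgi2 at -2.99.

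The epithelium-poor sections of dorsal tongue carried the same family at lower levels. Krtap9-1 was at 459 ± 90.0 CPM against 1.10 ± 1.22 in the other sites (SD, n = 2 and 6; log2 fold change 10.40 ± 0.87 SE, adjusted p = 0.0109). Gm11559 was at 182 ± 80.8 against 0.412 ± 0.474 and Gm11595 at 272 ± 71.5 against 2.14 ± 3.18. Gm11596 was at 287 ± 3.53 against 2.22 ± 3.01 and Krtap4-6 at 217 ± 27.7 against 1.99 ± 2.86. In each case 3 of the other samples had no UMI, so the folds depend on the prior count. Of 20 hard keratin genes 9 rose (13 adjusted over the list alone; fry adjusted p = 0.0881, which misses the threshold), with Krt86 at 7.58, Krt83 at 6.73, Krt33a at 7.27 and Krt34 at 6.89. Of 58 patterning transcription factors Hand2 (2.85), Tbx15 (1.54) and Nkx2-5 (3.46) rose and Meis2 fell by 2.04 (6 up and 6 down adjusted over the list alone). In all 97 genes were higher and 1 lower of 16821, of which 66 and 1 were also called in the epithelium-rich sections. Without buccal mucosa replicate 2 the counts were 308 and 42, including all 97 and 1. The count was 986 and 350 without buccal mucosa replicates 1 and 2. It was 1 without either dorsal or ventral tongue replicate, and 91 and 1 without hard palate replicates 1 and 2. Without hard palate among the other sites 27 genes passed, and Tbx15 turned to -0.43 (adjusted p = 0.735), while adjusted p was 0.302 for Meis2, 0.468 for Hand2, 0.553 for Nkx2-5, 0.0572 for Krtap9-1 and 0.0589 for Gm11596. The folds of Krtap9-1 (8.10) and Gm11596 (6.89) stayed large, while Meis2 was at -1.29, Hand2 at 1.34 and Nkx2-5 at 1.67.

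**Figure D4:**
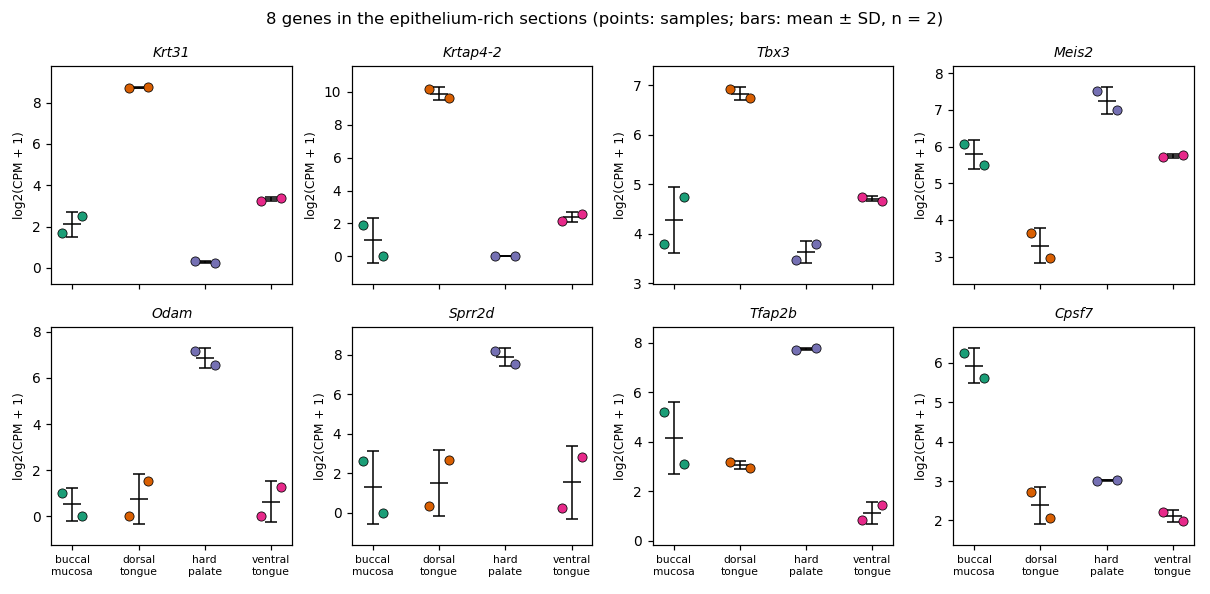
Log2(CPM + 1) of 8 genes (vertical axes) in the epithelium-rich sections of the 4 sites (horizontal axes); points are samples and bars the mean ± SD (n = 2). Krt31 lay at 422 CPM in dorsal tongue and 4.25 CPM elsewhere, and Odam at 117 CPM in hard palate and 0.726 CPM elsewhere.

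With all 8 samples hard palate differed from the other sites in more genes than any other site did, which did not hold in each fit without 1 sample. In its epithelium-rich sections Odam, a secreted protein of ameloblasts and of epithelium attached to teeth, was at 117 ± 34.8 CPM against 0.726 ± 0.839 (SD, n = 2 and 6; log2 fold change 7.21 ± 0.99 SE, adjusted p = 0.0131). The cornified envelope gene Sprr2d was at 242 ± 75.8 CPM against 2.87 ± 3.01 (6.30) and Cytl1 at 85.5 ± 20.4 against 3.03 ± 4.37 (6.23). U90926 was at 61.4 ± 20.8 against 0.931 ± 1.12 (5.97), and the alarmin S100a8 at 354 and 23.0 in replicates 1 and 2 against 4.64 ± 2.66. Some of the other samples had no UMI of Odam (3), Sprr2d (1) and U90926 (3), so those folds depend on the prior count. The largest falls were Pvalb of fast muscle (-9.62, 0.489 ± 0.139 CPM against 477 ± 580) and the genes Gm49425 (-9.32) and Gm11568 (-9.05). Both of the latter were high mainly in dorsal tongue. Gm49425 was at 441 and 483 CPM there and 1.56 to 22.5 in buccal mucosa and ventral tongue. Gm11568 was at 1372 and 1049 CPM in dorsal tongue and 0.479 to 5.91 in buccal mucosa and ventral tongue.

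By list, 30 of 36 skeletal muscle genes fell in epithelium-rich hard palate (32 adjusted over the list alone; fry adjusted p = 0.0528, which misses the threshold), with Myoz2 at -6.05, Tnnt1 at -6.51, Mybpc1 at -7.98 and Neb at -5.63. Of 20 hard keratin genes 10 fell and 1 rose (11 and 4 adjusted over the list alone; adjusted p = 0.0602), with Krt31 at -6.62, Krt83 at -5.71, Krt86 at -5.91 and Krt33a at -5.49, the other sites' level being set by dorsal tongue. Of 59 patterning transcription factors 9 rose and 6 fell (14 and 9 adjusted over the list alone; mixed adjusted p = 1.2e-05). On balance it did not pass (fry adjusted p = 0.233, adjusted p = 0.731 with an estimated correlation). Tfap2b rose by 5.17, Shox2 by 3.34 and Meis2 by 2.36, and Hand2 fell by 4.78. Of 35 antimicrobial genes 5 rose (7 rose and 1 fell adjusted over the list alone), including the chemokine Cxcl1 (3.60), the lectin Reg3g (5.38) and S100a9 (4.83). This list did not pass (fry adjusted p = 0.294). Of 43 cornified envelope genes Sprr2e (5.48), Sprr2d and Ivl (1.89) rose (4 adjusted over the list alone), and Flg2 was at 4.38 (adjusted p = 0.0586). In all 278 genes were higher and 543 lower of 16485. In the fit without buccal mucosa replicate 2 there were 868 and 1241, including all 278 and 543. The count was 4032 and 2109 without buccal mucosa replicates 1 and 2. It was 239 and 323 without those of dorsal tongue, 0 and 28 without those of hard palate, and 100 and 0 without those of ventral tongue (edgeR; 3377 genes at unadjusted p under 0.05 and 1732 by DESeq2 with all samples). None of the 26 named genes passed in every one of these fits, and by DESeq2 U90926 had adjusted p = 0.112.

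In the epithelium-poor sections of hard palate the same secreted and defence genes were higher and muscle genes were lower. Their keratinocyte scores averaged 8.94 and 8.63, against 4.14 to 8.37 in epithelium-poor sections of the other sites. The sections compared were thus not matched in keratinocyte transcripts. Odam was at 143 ± 12.8 CPM against 0.267 ± 0.256 (SD, n = 2 and 6; log2 fold change 8.77 ± 0.59 SE, adjusted p = 0.000798). Reg3g was at 21.5 and 204 in replicates 1 and 2 against 0.483 ± 0.665 (7.93). U90926 was at 88.5 ± 3.43 against 0.406 ± 0.248 (7.61). Sprr2d was at 291 ± 1.47 against 1.54 ± 1.53 (7.45) and the iron-binding protein gene Ltf at 146 ± 8.58 against 8.34 ± 18.2 (6.31). Except for U90926 these had 1 or 2 other samples with no UMI, so the folds depend on the prior count. The muscle genes Sypl2 and Trim63 fell by 8.97 and 8.89 (0.301 ± 0.425 CPM against 135 ± 48.4, and 0.276 ± 0.291 against 123 ± 57.3). Krtap4-9 fell by 8.90, with 623 and 517 CPM in dorsal tongue and at most 15.2 in the other sites. Of 36 skeletal muscle genes 31 fell (33 adjusted over the list alone), with Myoz2 at -6.34, Casq1 at -8.26, Mybpc1 at -7.47 and Casq2 at -3.98. By fry the list had adjusted p = 0.0325, adjusted p = 0.596 with an estimated correlation and 0.0674 without buccal mucosa replicate 2.

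Of 36 antimicrobial genes 10 rose and 2 fell in epithelium-poor hard palate (12 and 2 adjusted over the list alone; fry adjusted p = 0.0981), with Cxcl1 at 3.55, S100a9 at 5.89 and the cytokine Il1b at 2.97. Of 20 oral and stress-type keratins Krt1 (4.86) and Krt10 (2.71) rose (1 adjusted over the list alone), while Krt19 was at 1.92 and Krt24 at 2.67 (adjusted p = 0.0554 and 0.061). Near the UMI limit, Krt10 was at 4.61 and Krt24 at 5.42 in reads. Of 58 patterning transcription factors 13 rose and 7 fell (17 and 9 adjusted over the list alone; mixed adjusted p = 3.8e-05). On balance it did not pass (fry adjusted p = 0.307, adjusted p = 0.916 with an estimated correlation). Tbx15 fell by 5.77 (3.28 ± 0.465 CPM against 181 ± 41.3, SD) and Hand2 by 4.95, and Meis2 rose by 2.67 and Six2 by 2.27. Of 35 BMP and TGF-beta genes 9 rose and 3 fell (12 and 4 adjusted over the list alone), including Id2 (1.74), Bmp7 (2.59), Id3 (1.46) and Ltbp2 (2.26). Bone and cartilage genes also changed there, 8 of 20 up and 1 down (9 and 1 adjusted over the list alone; fry adjusted p = 0.142), and whether such tissue carried the BMP and TGF-beta genes was not tested. Of 21 adipocyte genes 7 fell (8 adjusted over the list alone), with the lipase Pnpla2 at -2.91, Gpd1 at -5.07, Plin4 at -4.82 and Aqp7 at -4.98. The list averaged 2.71 and 3.82 log2 units in hard palate replicates 1 and 2. It averaged 7.18 in buccal mucosa replicate 2 and 3.53 to 4.02 in the remaining samples, so hard palate replicate 2 lay within their range. In all 993 genes were higher and 1568 lower of 16821, of which 245 and 486 were also called in the epithelium-rich sections. Without buccal mucosa replicate 2 the counts were 1427 and 1844, including 933 and 1550 of these. The count was 4828 and 3271 without buccal mucosa replicates 1 and 2. It was 1200 and 1171 without those of dorsal tongue, 742 and 1385 without those of hard palate, and 1233 and 1436 without those of ventral tongue. In all, 23 of the 31 named genes passed in all of these fits.

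Buccal mucosa had few calls in the epithelium-rich sections, where its replicates differed most. Cpsf7, a subunit of a complex that cleaves the 3' ends of messenger RNAs (chromosome 19, 10525266 to 10547653, GRCm38), was at 74.9 and 47.9 CPM in replicates 1 and 2 against 4.92 ± 1.93 (SD, n = 6; log2 fold change 3.71 ± 0.28 SE, adjusted p = 0.0254). The homeobox gene Irx5 (4.18, adjusted p = 0.0477) and Lrmp (2.86, adjusted p = 0.0254) also rose. Lrmp lay outside the rule and is named because only 3 genes passed. Irx5 was the 1 of 59 patterning transcription factors that passed (12 up and 5 down adjusted over the list alone), with Shox2 at 2.83, Irx2 at 5.72 and Zic1 at 6.25 (adjusted p = 0.101, 0.106 and 0.119). Of 16485 genes 3 were higher and 0 lower by edgeR, 2721 had an unadjusted p under 0.05 and DESeq2 called 930. In the fit without buccal mucosa replicate 2 70 genes were higher and 32 lower, including these 3. The count was 4361 and 102 without buccal mucosa replicates 1 and 2. It was 0 without any 1 of the other 6 samples. Without hard palate among the other sites 18 genes passed.

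In the epithelium-poor sections of buccal mucosa some muscle genes were higher than the mean of the other sites, a mean that includes hard palate. Actn3 was at 25.2 and 496 CPM in replicates 1 and 2 against 8.15 ± 5.80 (SD, n = 6; log2 fold change 5.74 ± 0.82 SE, adjusted p = 0.0282). Mybpc2 was at 100 and 337 against 22.1 ± 20.1 (5.11) and Oit1 at 11.3 and 239 against 4.39 ± 2.45 (5.01). The growth inhibitor of muscle Mstn was at 19.5 and 103 against 4.73 ± 3.70 (4.96), and Tmem233 at 37.9 and 98.8 against 7.85 ± 7.96 (4.26). The cornification gene Flg fell by 5.36 (10.4 and 1.54 CPM against 292 ± 176), the growth factor gene Epgn by 4.53 and Rnase2b by 3.63. Of 36 skeletal muscle genes 18 rose (31 adjusted over the list alone), with Myoz2 at 2.31, Casq1 at 3.65, Ttn at 2.81 and Actn2 at 2.97. As a list they missed the threshold (fry adjusted p = 0.0981). Of 58 patterning transcription factors Zic1 (7.81; 9.74 ± 1.49 CPM against 0.0382 ± 0.0655, with no UMI in 4 other samples), Tbx15 (1.94) and Irx5 (4.33) rose (10 up and 5 down adjusted over the list alone).

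On average over their lists, salivary gland and adipocyte genes were higher in buccal mucosa replicate 2 than in the other 7 samples, though not every member was. None of 25 salivary gland genes passed by edgeR (17 up and 1 down adjusted over the list alone), with Bpifa2 at 2600 ± 3654 CPM against 4.30 ± 5.70 (SD; adjusted p = 0.0638), Agr2 at 490 ± 692, Lman1l at 222 ± 314 and Kcnn4 at 51.7 ± 69.8. Of 21 adipocyte genes Gpd1 rose by 3.06 (16 adjusted over the list alone), and Car3 was at 977 ± 1352 CPM against 18.3 ± 28.3 (adjusted p = 0.0607). In all 213 genes were higher and 30 lower of 16821 in epithelium-poor buccal mucosa. Without replicate 2 there were 122 and 20, including 99 and 8 of these. Then Actn3 was at 2.38 (adjusted p = 0.0199), Mstn at 3.33 (0.0545), Oit1 at 1.56 (0.213) and Rnase2b at -3.46 (0.153). The count was 3636 and 142 without buccal mucosa replicates 1 and 2. It was 179 and 93 without those of hard palate, and 0 without any 1 sample of dorsal or ventral tongue (edgeR; 3256 genes at unadjusted p under 0.05 and 1226 by DESeq2 with all samples). Against dorsal and ventral tongue alone 0 genes passed, with adjusted p of 0.19 for Actn3, 0.734 for Myoz2 and 0.0821 for Zic1. Of the folds, Oit1 (5.25), Flg (-5.13), Epgn (-4.96) and Rnase2b (-3.70) stayed about as large, while Actn3 was at 4.46, Mybpc2 at 2.79 and Myoz2 at 0.22.

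Ventral tongue had more Hand2 than the mean of the other sites and, in epithelium-poor sections, more of some muscle transcripts than this mean, which includes hard palate. In the epithelium-rich sections no gene met the rule for naming. The patterning factor Hand2, at 37.6 ± 2.24 CPM against 7.66 ± 10.1 (SD, n = 2 and 6; log2 fold change 3.84 ± 0.29 SE, adjusted p = 0.038), was the 1 gene that passed. Among the other patterning factors Tfap2b was at -4.67, Osr2 at 1.54 and Shox2 at -3.58 (adjusted p = 0.112 for each; 8 of 59 up and 5 down adjusted over the list alone). Of 16485 genes 1 was higher and 0 lower by edgeR, with 1292 at unadjusted p under 0.05 and 288 by DESeq2. In the fit without buccal mucosa replicate 2 569 genes were higher and 83 lower, Hand2 included. The count was 882 and 652 without buccal mucosa replicates 1 and 2. It was 0 without any 1 of the other 6 samples. Without hard palate among the other sites 0 genes passed, and Hand2 was at 2.53 (adjusted p = 0.558).

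In the epithelium-poor sections of ventral tongue the largest rises were the non-coding RNA Gm49668 (62.5 ± 10.4 CPM against 12.2 ± 11.8, SD, n = 2 and 6; log2 fold change 3.98 ± 0.40 SE, adjusted p = 0.00891) and Lrrc30 (139 ± 11.6 against 38.8 ± 35.9; 3.80). They were followed by 2310065F04Rik (389 ± 37.9 against 109 ± 97.2; 3.62), Sbk2 (604 ± 159 against 178 ± 143; 3.52) and Nctc1 (3.43). The CPM means of these genes were, in order, only 5.14, 3.58, 3.58, 3.4 and 2.89 times those of the other sites. Hard palate had at most 3.01 CPM of each, which lowers the mean of the logs. Id2, an inhibitor of basic helix-loop-helix factors, fell by 1.44 (33.2 ± 0.382 CPM against 102 ± 57.7). Of 36 skeletal muscle genes 14 rose (30 adjusted over the list alone), with Myoz2 at 2.08, Casq2 at 2.07, Mybpc1 at 2.91 and Neb at 2.46. As a list they missed the threshold (fry adjusted p = 0.0981). Of 58 patterning factors Hand2 (3.59), Tbx15 (2.28) and Nkx2-5 (3.01) rose, and Irx3 was at -2.24 (adjusted p = 0.0542; 6 up and 4 down adjusted over the list alone). In all 423 genes were higher and 3 lower of 16821. Without buccal mucosa replicate 2 there were 811 and 62, including 422 and 3 of these. The count was 1144 and 873 without buccal mucosa replicates 1 and 2. It was 249 and 267 without those of hard palate, and 0 without any 1 tongue sample (edgeR; 2215 genes at unadjusted p under 0.05 and 890 by DESeq2 with all samples). Against buccal mucosa and dorsal tongue alone 0 genes passed, adjusted p was 0.9996 for each gene named here, and Myoz2 turned to -0.04. The folds fell to 1.80 for Gm49668, 1.29 for Lrrc30, 1.26 for 2310065F04Rik, 1.20 for Sbk2, 0.98 for Nctc1 and -0.97 for Id2.

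Dorsal and ventral tongue, compared directly, differed by hard keratins in the epithelium-rich sections. Gm11563 was at 320 ± 110 CPM in dorsal and 1.31 ± 0.0397 in ventral tongue (SD, n = 2 each; log2 fold change 7.92 ± 0.67 SE, adjusted p = 0.0457). Krt33a was at 129 ± 15.6 and 0.736 ± 0.037 (7.43) and Krt86 at 484 ± 10.3 and 3.44 ± 0.555 (7.13). Krt31 was at 422 ± 2.73 and 9.04 ± 0.663 (5.54) and Krt87 at 871 ± 151 and 18.9 ± 8.17 (5.52). Of 20 hard keratin genes 4 rose (13 adjusted over the list alone), Krt83 being the remaining one at 5.37. In all 8 genes were higher and 0 lower in dorsal tongue by edgeR (850 at unadjusted p under 0.05, 165 by DESeq2). With the replicate number as a block 0 genes passed. The buccal mucosa samples enter this comparison through the shared spread, the filter on low counts and the scaling. The count was 194 and 205 without buccal mucosa replicates 1 and 2. It was 1 without either hard palate sample and 0 without any 1 tongue sample. In the epithelium-poor sections 0 genes passed by edgeR, with 584 at unadjusted p under 0.05 and 58 by DESeq2, and 30 higher and 3 lower without buccal mucosa replicate 2 (33 genes also without replicate 1).

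A test of any difference between the 4 sites called 321 genes in the epithelium-rich sections, 1170 in the epithelium-poor sections and 886 of 18609 over all sections. These counts without buccal mucosa replicate 2 were 1684, 1962 and 2429. In the epithelium-rich sections the count was 4670 without buccal mucosa replicate 1, 27 and 33 without the dorsal tongue, 24 and 42 without the hard palate and 3 and 3 without the ventral tongue replicates. In the epithelium-poor sections it was 4383 without buccal mucosa replicate 1 and 341 and 329, 258 and 314, and 342 and 378 in the same order. Over all sections it was 5684 without buccal mucosa replicate 1, and 0 and 0, 0 and 7, and 1 and 1 in the same order. The difference between the regions depended on the site for 10 genes of 15174, among them Mucl2, Msx2, Krt1 and Krt17. Leaving out a sample gave 234 and 269 genes without the buccal mucosa replicates, 4 and 0 without those of dorsal tongue, 19 and 11 without those of hard palate and 4 and 2 without those of ventral tongue.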

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

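The tests in this part were chosen before the data were examined. The difference between the regions depended on the site for 10 genes (edgeR interaction test over the 4 sites, n = 2 samples per site). Each is given with the log2 fold change of epithelium-rich over epithelium-poor sections within a site.

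Genes of secreted proteins went opposite ways. Mucl2 (adjusted p = 0.00518) was at -5.04 in buccal mucosa, 4.95 in dorsal tongue and 2.26 in hard palate, and it was also lower in the epithelium-rich sections of ventral tongue. Scgb2b27 (0.0118) was at -5.89, 6.73 and 0.28 in the same order and -5.23 in ventral tongue. Scgb1b27 (0.0271) was at -5.97, 6.84, 2.00 and -6.51 in these 4 sites. In each tongue or cheek site 1 of the 2 samples carried these values. Mucl2 was at 489 CPM in the epithelium-poor sections of buccal mucosa replicate 1 and 3.43 in those of replicate 2. It was at 320.0 in the epithelium-poor sections of ventral tongue replicate 2 and 0 in replicate 1, and at 506 in the epithelium-rich sections of dorsal tongue replicate 2 and 0.0641 in those of replicate 1. By DESeq2 Mucl2 had adjusted p = 0.673. In the same samples the mean level of the salivary gland list, which includes Scgb2b27, differed between the regions by -1.26 (buccal mucosa replicate 1), -1.13 (ventral tongue replicate 2) and 0.897 log2 units (dorsal tongue replicate 2). In the other replicates of these sites it differed by 0.289, 0.018 and 0.235. Whether gland tissue in 1 sample of each site carried these genes was not tested.

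The homeobox gene Msx2 (adjusted p = 0.0126) was at 4.07 in buccal mucosa and 0.44, 0.42 and -0.73 in dorsal tongue, hard palate and ventral tongue. Smoc2 (0.0251) was at -1.81 in dorsal tongue and 0.10, -0.16 and 0.35 in buccal mucosa, hard palate and ventral tongue. Krt17 (0.0271) was at 2.41 in buccal mucosa and 0.59, 0.69 and 0.21 in the others. Krt1 (0.0271) was at 4.73 in buccal mucosa, which rests on replicate 1 (529 CPM in epithelium-rich and 18.2 in epithelium-poor sections; 0.957 and 0.685 in replicate 2), and by DESeq2 it had adjusted p = 0.433. The hard keratins Krt83 (0.0271) and Krt87 (0.0295) and the keratin-associated Krtap13-1 (0.0266) were higher in the epithelium-rich sections of dorsal tongue, at 1.46, 1.44 and 1.28, and lower in those of ventral tongue, with Krt87 at -1.07 and Krtap13-1 at -0.75.

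In the difference between the regions of the mean level of a list, 1 sample lay far from the other 7 in 2 of 28 lists, where chance gives about 1 in 20. For antimicrobial genes hard palate replicate 2 was at -0.614 log2 units and the others at -0.06 to 0.346, a gap of 0.577 of the whole range. For oral and stress-type keratins buccal mucosa replicate 1 was at 1.20 and the others at 0.204 to 0.492, a gap of 0.71 of the range.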

How the results depend on the processing

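In this part the first against the last 5 sections and the other sites without hard palate were chosen after the data were seen. Without hard palate the mean of the other sites holds fewer samples, and the cause of the changes was not tested: 18 genes passed in epithelium-rich buccal mucosa (3 with it), 112 in dorsal tongue and 0 in ventral tongue, and in epithelium-poor sections 0, 27 and 0. Among 82 named results with this setting 37 kept their side of the threshold, 42 lost it and 1 gained it. The direction turned in 2, Myoz2 in ventral tongue (-0.0393) and Tbx15 in dorsal tongue (-0.4284), both in epithelium-poor sections. No other setting turned one. Over all settings 3629 of 4332 named results kept direction and side, 612 lost the threshold and 89 gained it.

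Counts are given for epithelium-rich sections as any difference between sites, buccal mucosa, dorsal tongue, hard palate, ventral tongue, and dorsal against ventral tongue. DESeq2 called 1960, 930, 440, 1732, 288 and 165 genes, and no filter on low counts gave 3213, 1817, 1098, 2431, 787 and 370. In epithelium-poor sections DESeq2 called 2976 (any), 1226 (buccal mucosa), 408 (dorsal tongue), 890 (ventral tongue) and 58 (dorsal against ventral), and no filter gave 4472, 2496, 937, 4126 (hard palate), 1285 and 205. Over all sections they gave 3294 and 4522, and for the interaction 203 and 1035. Without the filter the estimated prior degrees of freedom became infinite, against 3.23 with it in epithelium-rich sections. The cause of the other differences was not tested.

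Reads in place of UMIs gave 3 genes for dorsal against ventral tongue in epithelium-rich sections, and 9 lists by site in each region against 1. With no running median dorsal tongue replicate 1 had 1 epithelium-poor section of 2523 UMIs, on which the epithelium-poor and interaction counts rest. In that setting 5 genes passed in epithelium-rich ventral tongue, 16 between dorsal and ventral tongue, 400 in epithelium-poor buccal mucosa, 60 in dorsal tongue and 227 for the interaction, and 0 lists by site in epithelium-poor sections and 2 by region. Regions by Krt5 and Krt14 gave 1 gene in epithelium-rich buccal mucosa, 3399 between the regions, 1 for the interaction, 2 lists by site in epithelium-poor sections and 3 by region. The top 1 in 3 sections by score gave 184 genes for any difference in epithelium-rich sections, 4 for dorsal against ventral tongue, 0 for the interaction and 4 lists by site in epithelium-poor sections. The first against the last 5 sections gave 77, 0, 111, 39, 0 and 5 genes in the order above, 478 in epithelium-poor buccal mucosa and 2 for the interaction. Epithelium-poor sections within 10 numbers gave 1 gene between dorsal and ventral tongue. Camera with an estimated correlation called 0 lists by site in epithelium-poor sections and 0 by region. The cause was not tested in these cases.

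The replicate numbers of the labels were not taken to pair the samples. Replicate differences of 2 sites ran together in dorsal and ventral tongue (correlation 0.433 and 0.471), a hint of pairing there, and correlated at -0.242 to 0.2 for other pairs of sites. With the replicate number as a block 60 genes passed for any difference, 96 in dorsal tongue, 445 in hard palate, 0 in ventral tongue and 0 between dorsal and ventral tongue in epithelium-rich sections. In epithelium-poor sections 599, 68 (buccal mucosa), 58 (dorsal tongue) and 172 (ventral tongue) passed, 362 over all sections, and 0 lists by site in epithelium-poor sections. Between the regions the sample was already the block.

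With 1 sample left out, a site with a lone sample was taken to vary like the others. The filter and the scaling were also redone, so the genes tested changed. In epithelium-rich sections 17333 were tested without buccal mucosa replicate 2, against 16485 with all samples. In epithelium-rich sections the counts ran from 3 to 4670 (any difference), 0 to 4361 (buccal mucosa), 46 to 1530 (dorsal tongue), 0 to 4032 (hard palate), 0 to 882 (ventral tongue) and 0 to 205 (dorsal against ventral). In epithelium-poor sections they ran from 258 to 4383, 0 to 3636, 1 to 986, 742 to 4828, 0 to 1144 and 0 to 33, over all sections from 0 to 5684, between the regions from 4002 to 6161 and for the interaction from 0 to 269. Lists by site passed in 1 to 31 cases in epithelium-rich and 0 to 20 in epithelium-poor sections, and by region in 6 to 13. The high values came without a buccal mucosa sample, where the common dispersion in epithelium-rich sections was 0.0884, against 0.182 with all samples and 0.220 to 0.236 without another sample. RLE scaling, estimated transcripts and section minima of 300 and 3000 UMIs kept every count within 1.5 times. The minimum of 300 removed no section. Near and far epithelium-poor sections could be compared at 5 numbers only, and the other settings fixed for that comparison were not run. At the spread simulated for 1 site against the others 3% of 2-fold changes were found, so differences of that size were mostly not detectable with 2 samples per site.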

Other observations

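The tests here chosen only after the result was seen were the epithelium share, the transcription factor distance, the reads per UMI of Cpsf7, the rise of the neutrophil genes, the tooth surface genes and the other splits of the samples. The single-gene values of buccal mucosa replicate 2 were also picked after the fact.

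Within the epithelium-poor sections, those up to 5 numbers from an epithelium-rich section differed from those farther away in 5 samples with enough of both (both buccal mucosa, dorsal tongue replicate 2 and both ventral tongue). Near sections had more of the fatty acid binding protein Fabp5 (log2 0.65 ± 0.17 SE; 494 ± 318 CPM against 347 ± 255, SD, n = 5; edgeR adjusted p = 0.0357), Rps26-ps1 (0.63), Hacd2 (0.57), the retinoic acid binding protein Crabp2 (0.53), Scgb1a1 (0.53) and the adhesion gene Nectin1 (0.51). They had less of the muscle genes Actn3 (-1.10), Mybpc2 (-0.83), Ampd1 (-0.73), Mylk2 (-0.68), Mylk4 (-0.63) and Cacna2d1 (-0.57). The rule for naming required the same sign in 5 of 5 samples. Of 13899 genes 242 were higher and 450 lower near. As lists, 16 of 36 skeletal muscle genes were lower near and 3 of 20 keratinocyte genes higher, with fry adjusted p = 0.0814 for both, which misses the threshold. Distance was counted from sections chosen by the score of these 20 keratinocyte genes, so the contrast is not independent of that score.

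Buccal mucosa replicate 2 also differed from replicate 1 in single epithelial genes. The homeobox gene Nkx2-3 had no UMI in it, which allows up to 1.57 CPM in its epithelium-rich sections, against 168 CPM in replicate 1 and 0 to 135 CPM in the samples of other sites. Krt5 was at 98.1 CPM, Krt13 at 74.2 and Krt4 at 28.2, against at least 1970, 3480 and 2440 in each sample of the other sites. The inner root sheath keratins of hair Krt25 (161 CPM), Krt71 (111) and Krt27 (27.3) and the simple epithelial keratins Krt8 (31.6) and Krt18 (409) were higher there than in any other sample, where they reached at most 0.168, 1.09, 1.37, 0.71 and 4.16 CPM in the other sites. The transcription factors Irx1 and Irx2 were at 45.5 and 50.7 CPM, against 0.938 and 3.44 in replicate 1.

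Of 3 explanations weighed for why replicate 2 of buccal mucosa stood apart, its lower depth is argued against: replicate 1 thinned to the same UMIs correlated with ventral tongue replicate 1 better than replicate 2 did, by 0.135 in Spearman correlation across genes (0.936 against 0.801). A lower share of epithelium alone would raise other cell types alike, but salivary gland genes exceeded endothelial genes by 1.98 log2 units in the ratio of replicate 2 to 1 (95% bootstrap interval 0.237 to 6.62). A sample of another of the 4 sites cannot be told apart. Genes higher in buccal mucosa without replicate 2 were taken first. Replicate 2 lay above all 6 samples of other sites for 21 of 70 (epithelium-rich) and 58.2% of 122 (epithelium-poor). For genes higher in ventral tongue it lay above all samples outside ventral tongue, replicate 1 included, in 70.3% and 61.4%. Fisher's exact test in epithelium-poor sections (two-sided, p = 0.55) thus compared shares counted against different samples and cannot decide this. The ventral tongue genes also included 23 and 27 of 36 skeletal muscle genes, a list highest in replicate 2 (9.05 and 9.81 log2 units). In patterning factors the nearest other site lay farther than replicate 1 by 0.0149 (hard palate, epithelium-rich, interval -0.703 to 0.65) and 0.448 (ventral tongue, epithelium-poor, -0.0368 to 0.962). Dorsal tongue lay farther by 0.515 (epithelium-rich, 0.112 to 0.927) and 0.619 (epithelium-poor, 0.165 to 1.07), with intervals that excluded no difference. Those of hard palate and ventral tongue included it in both regions. Cpsf7 (47.9 CPM, at most 7.17 in other sites, epithelium-rich) and Zic1 (10.8 CPM, at most 0.159, epithelium-poor) ran with its label. They were named from fits that include replicate 2, so they cannot decide it. Tissue taken at another spot of the cheek, with gland, fat or hair-bearing skin, may also account for it and was not tested.

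Cpsf7 was higher in both buccal mucosa samples, and 3 technical explanations were tested. In each of the 2 samples 20 of 20 sections lay above the highest whole-sample value elsewhere, 9.02 CPM, which argues against a few sections with many UMIs. Its reads per UMI in these samples were at most 0.851 times those of all genes of the sample. They were 2.11 and 2.02 in replicates 1 and 2, however, above the 1.06 to 1.3 of the same gene in the other sites. These 2 comparisons point different ways. The rise itself was in distinct UMIs, however, where repeated reads of 1 UMI count once. They numbered 1260 and 329 in replicates 1 and 2, against 51 to 238 in the samples of other sites. These numbers argue against duplicated reads of few molecules as the source of the rise. The 7 tested genes within 100 kb had a median log2 fold change of 0.147 (bootstrap interval -0.039 to 0.255), which argues against a change of the neighbourhood, although Syt7 was at 3.90 (adjusted p = 0.119). A difference of this gene between the cheek and the other sites may remain as a hypothesis, as may a genetic difference between the mice used, which was not tested.

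Some alarmin and defence genes, picked after they were seen to rise, were higher in both hard palate samples. Over all sections S100a8 was at 350.0 and 30.8 CPM, against at most 6.77 elsewhere, and Cxcl1 at 20.7 and 14.2, against at most 2.57. The antimicrobial list as a whole did not pass in hard palate in either region (fry adjusted p = 0.294 in epithelium-rich sections). Neutrophils in the tissue cannot be ruled out as the source of S100a8 and S100a9. Of the 6 measured members of a neutrophil list written for this test, 1 lay above all 6 other samples, Csf3r at under 1 CPM. The 6 rose by a median of 0.419 and 0.623 log2 units in replicates 1 and 2 (95% bootstrap intervals up to 1.08 and 1.66), against at least 6.0 and 2.76 for S100a8 and S100a9. But Csf3r, Cxcr2, Retnlg and Clec4d were at only 0.728 to 2.62 CPM in hard palate, too near the floor to decide. Il1r2 was at 12.5 to 41.9 CPM in every sample. Ngp, which did not pass the filter, also lay above all 6 (0.146 and 0.13 CPM). Epithelium at the tooth surface cannot be told apart, since of Odam and Amtn 1 gene lay above the other samples: Odam did, and Amtn was near the floor in all samples. Stress-type keratin and alarmin expression of the palate's own epithelium may also account for it and was not tested.

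Whether other splits of the samples give as many genes was counted in 80 splits in all. Exchanging the regions within samples gave at most 1399 genes in 29 other draws, against 5395 for the real regions (1 of 30 splits as large, of 128 possible). Other splits of the 8 samples into 4 pairs gave at most 269 genes in epithelium-rich and 577 in epithelium-poor sections, against 321 and 1170 for the real sites (1 of 25 splits as large in each, of 105 possible). For the sites no other split drawn gave as many genes, and 1 of 25 is the smallest share these draws can give. Most of the 105 possible splits were not drawn, so chance is not excluded. The epithelium-rich count was 3 to 42 without any 1 sample of dorsal tongue, hard palate or ventral tongue. The regions were drawn from the expression of the same sections, so their count says nothing of chance.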
